A study of Mus musculus with 7 samples.

How the data were processed

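RNA was measured in 7 libraries of Vγ6+ γδ T cells sorted by flow cytometry from mouse ear skin. Of these, 3 libraries were controls and 4 came from mice whose skin had been associated topically with Staphylococcus aureus. The treatment labels of the controls give association with growth medium, while their titles and columns call them naive; they were taken here as medium controls, and the labels do not settle whether they were untreated. Cells were taken 14 days after the first application, per the labels. Per the labels' protocols, RNA came from an RNeasy Plus Micro kit, and libraries of polyadenylated RNA were made with the SMARTer Ultra Low Input and Nextera XT kits, which amplify full-length cDNA from few cells and do not mark the strand. The submitters' processing notes name STAR, HOMER, DESeq2 and the mouse build mm10, without versions or settings.

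The authors deposited 1 table of TPM values with 24537 rows, each a RefSeq transcript standing for 1 gene, and 7 value columns, all of which were used. The columns taken as S. aureus replicates 3 and 4 do not have the same form of name as their samples: 1 carries the added letters EDM, whose meaning is not given in the sources used here, and 1 lacks a letter of the replicate tag. Per the file headers it gives a position, a length and a symbol for each row in addition to the TPM. Summed over rows, the deposited TPM came to between 704062 and 746204 per library. The length in the table equalled the genomic span from start to end, introns included, in 99.3% of rows. Multiplying each TPM by that span gave whole multiples of 1 step per library, within 0.1 of a step for 100% of the 1277 to 2046 low values checked in each library. The deposited TPM was therefore scaled by genomic span, so that TPM of genes with long introns is understated and levels of different genes are not directly comparable, while the ratio of 1 gene between libraries differs from that of TPM on exonic length by a factor common to all genes of a library. Median-ratio scaling, run as an alternative, takes out such a factor. The same steps gave the relative depth: 51223851, 54652950 and 54968552 read units in control replicates 1, 2 and 3, and 32783024, 28953028, 34932090 and 43635615 in S. aureus replicates 1, 2, 3 and 4. Control libraries were thus deeper than S. aureus libraries. Between 58.8% and 66.0% of these low values were even numbers of units, so a unit may be a mate of a read pair rather than a whole fragment. At a span of 10 kb, 1 unit was worth between 0.0093 and 0.0195 TPM, so values near that size rest on few reads. Within a library, the same TPM rests on fewer reads in a gene of short span than in a gene of long span.

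A spreadsheet had turned 26 gene symbols into dates; all 26 were restored from the RefSeq identifiers of their rows. Of the 24537 identifiers, 24297 were found in the RefSeq gene table of build GRCm38.p6, which shares its coordinates with mm10. Positions are given as in the deposited table, on mm10, counted from 1. T cell receptor chain genes, mitochondrially encoded genes and immunoglobulin constant genes were not analysed here.

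Differences between groups were computed on log2(TPM + 1) with limma 3.58.1 in R 4.3.3 (moderated statistics with an intensity trend in the prior variance), comparing the 4 S. aureus with the 3 control libraries without covariates. The 11455 genes with a mean of at least 1 TPM over the 7 libraries were tested. A gene is called higher or lower where its Benjamini-Hochberg adjusted p is under 0.05. Fold changes on this scale understate the change of genes near or under 1 TPM; ratios of mean TPM are given beside them. Means are given ± SD over 3 control and 4 S. aureus libraries. The labels do not say whether each library came from separate animals or from pooled ears, so p-values measure the spread between these libraries only.

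Gene lists were written before the data were examined: 28 program lists, 1 list of receptor complex chains, and lists for other cell types and for RNA quality. Lists with at least 5 measured members were tested with camera, which asks whether the members of a list moved differently from all other genes, at a preset correlation of 0.01 between genes; adjustment was over the 28 program lists, and separately over 12 lists of other cell types and RNA quality. Camera was repeated with the correlation estimated from the data and on ranks, and fry tested whether members moved on balance one way. For lists of other cell types and RNA quality, the mean log2(TPM + 1) per library was compared by a two-sided exact permutation test over all 35 assignments of the 7 libraries to groups of 3 and 4, whose smallest possible p is 0.0286.

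The genes named in the text follow a rule set in advance. It takes the 10 largest changes in each direction among called genes whose groups did not overlap and whose higher group mean was at least 5 TPM, leaving out predicted genes, small RNAs, receptor variable segments and olfactory receptors. It adds 15 genes named whatever their result, up to 4 called members of each program list by smallest p (or 2 given as values where none was called), and the 2 most abundant members of each list for another cell type. Any other gene named was chosen after its values were seen. Results for 4 of the genes under this rule are not reported here, although they remain in the fits, lists and counts.

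The fit was tested on simulated libraries built from these 7 for this comparison, with the real depths and spread. Of 98 genes changed 2-fold, 21.4% were called, and of 93 changed 4-fold, 63.4% were called, in a run over 11209 genes; 3 of 83 calls were false. A list raised 2-fold was called, and 0 of 27 unchanged lists were. The simulated genes were drawn independently of each other, so this run does not test list calls where genes of a list move together. Alternatives planned in advance covered the pseudocount, the filter, 2 scalings, the variance model, library weights, a replicate block, leaving out each library and the list tests. A count test was planned in case whole reads could be used; it was not run, because the deposited unit is TPM. Alternatives added after seeing the data were limma voom on the recovered units, a keratinocyte marker mean as a covariate, and leaving out control replicate 1 and S. aureus replicate 4 together. Tables were handled with Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and SciPy 1.17.1.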

Results

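Vγ6+ γδ T cells are innate-like lymphocytes of the skin dermis and other barrier tissues that carry an invariant receptor and are known as producers of interleukin-17. Their transcriptomes were measured by RNA sequencing of cells sorted from mouse ear skin, 14 days after the first topical application of S. aureus (4 libraries) or from controls (3 libraries). The controls are labelled as given growth medium but titled naive. The comparison asks how these cells differed after association of the skin with this staphylococcus. Relative depth recovered from the deposited TPM was 51223851 to 54968552 read units in control libraries and 28953028 to 43635615 in S. aureus libraries. Between 10207 and 11625 genes reached 1 TPM per library.

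The 2 groups separated along the first principal component, which held 43.8% of the variance of log2(TPM + 1). Control replicates 1, 2 and 3 lay at 63.7, 52.8 and 22.4 on it, and the S. aureus libraries between -48.5 and -29.3. The second component, with 18.1% of the variance, set S. aureus replicate 4 at 49.98 and S. aureus replicates 1 to 3 between -31.9 and -14.5. Pearson correlations across genes, which are not independent replicates, were 0.919 to 0.936 between control libraries, 0.932 to 0.966 between S. aureus libraries and 0.864 to 0.924 across the groups. Control replicate 3 correlated with S. aureus replicate 3 (0.924) more closely than control replicate 1 did with control replicates 2 and 3 (0.921 and 0.919).

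The expression of 1416 genes differed between the groups: 667 were higher and 749 lower in the S. aureus libraries. The genes that rose most included interferon-inducible GTPases (Iigp1, Tgtp1 and Gbp3), the inhibitory receptor Ctla4 and the calcium-binding alarmins S100a8 and S100a9. Those that fell most included the TNF family cytokine Tnfsf11 (RANKL), the urokinase receptor Plaur, the survival factor Bcl2 and the adrenergic receptors Adra2c and Adrb1. Of the 1416 genes, 393 were more than 2-fold higher and 547 more than 2-fold lower on the log2(TPM + 1) scale. Limma called 12.4% of the 11455 genes tested, and 1412 of the called genes had groups that did not overlap; over all tested genes 27.4% did not overlap, where chance gives 5.71%. The number of calls fell to 360 higher and 328 lower without control replicate 2, and ranged up to 861 higher without S. aureus replicate 4 and 919 lower without control replicate 3. The median log2 fold change of all tested genes was -0.11, and a median-ratio scaling moved it to -0.01 and quantile normalization to 0.03, so changes smaller than this shift have no fixed direction.

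Ctla4 (NM_009843, chromosome 1, 60909025 to 60915832) went from 0.299 ± 0.518 TPM in control to 78.8 ± 33.7 TPM in S. aureus libraries, a log2 fold change of 5.93 (SE 0.36, limma adjusted p = 3.84e-05). S100a8 (NM_013650, chromosome 3, 90669071 to 90670034) had the largest log2 fold change under the naming rule, 6.30 (SE 0.72, limma adjusted p = 0.00148), from 0.848 ± 1.47 to 157 ± 117 TPM, and S100a9 went from 0.623 ± 1.08 to 42.7 ± 29.1 TPM. AW112010, an interferon- and inflammation-induced transcript (NR_102366, chromosome 19, 11047612 to 11050566), rose 49.9-fold in mean TPM, from 22.1 ± 6.43 to 1105 ± 398. Iigp1 rose from 0.366 ± 0.341 to 49.6 ± 7.90 TPM, Gbp3 from 1.49 ± 0.428 to 49.6 ± 4.02 and the interferon-induced receptor transporter Rtp4 from 0.635 ± 0.467 to 56.7 ± 10.3. Tgtp1 rose from 3.54 ± 1.69 to 146 ± 24.0 TPM, a value that reads of its near-identical neighbour Tgtp2 can share. The 4-transmembrane genes Ms4a4b (1.08 ± 0.145 to 49.5 ± 7.46 TPM) and Ms4a6b (1.54 ± 0.351 to 54.6 ± 10.8 TPM) completed the 10 largest increases.

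Tnfsf11 (NM_011613, chromosome 14, 78277446 to 78308043) fell from 98.7 ± 31.0 to 3.94 ± 2.19 TPM, a log2 fold change of -4.41 (SE 0.38, limma adjusted p = 0.000303). Plaur (NM_011113, chromosome 7, 24462483 to 24475968) fell from 56.6 ± 6.68 to 2.19 ± 1.52 TPM. Bcl2 was 14.2-fold lower in mean TPM (186 ± 75.3 against 13.1 ± 5.53) and Ramp3, a subunit that modifies adrenomedullin and calcitonin family receptors, 9.29-fold lower (203 ± 53.7 against 21.9 ± 2.49). Adra2c fell from 23.2 ± 13.1 to 1.29 ± 1.42 TPM, Adrb1 from 38.2 ± 17.3 to 3.82 ± 2.26, and the short-chain fatty acid receptor Ffar2 from 17.7 ± 12.7 to 0.601 ± 0.733. Rnf39, Olfml3 and Pxdc1 had log2 fold changes of -3.89, -3.78 and -3.14. All 20 of these genes were called under each of the other settings that tested them.

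**Figure D1:**
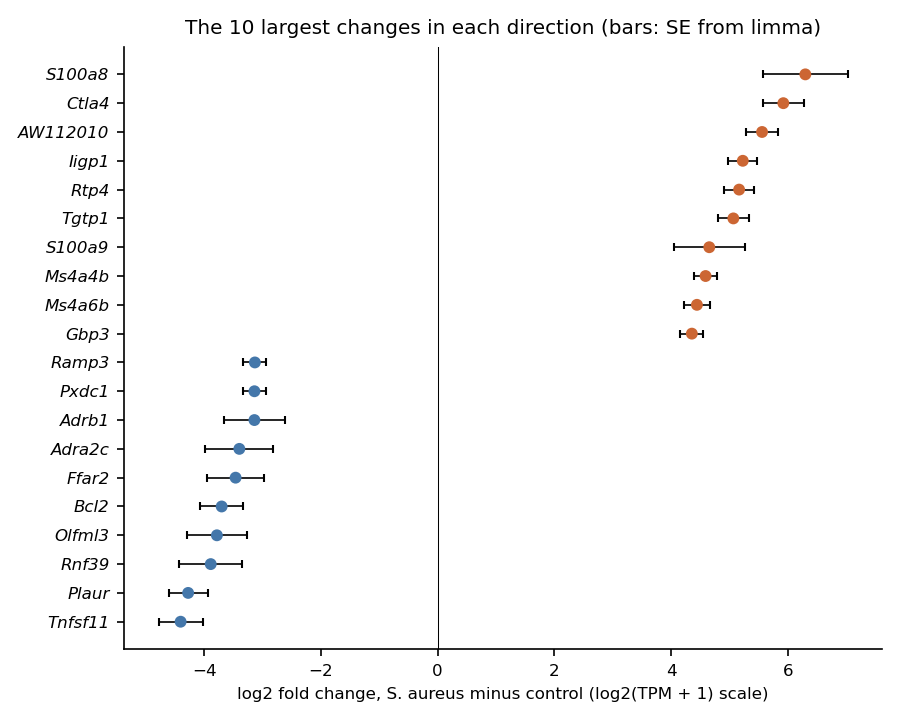
Log2 fold change (S. aureus minus control, on the log2(TPM + 1) scale, horizontal axis) of the 10 genes with the largest increase and the 10 with the largest decrease under the naming rule, with SE bars from limma. Increases ran from 4.36 for Gbp3 to 6.30 for S100a8 and decreases from -3.13 for Ramp3 to -4.41 for Tnfsf11.

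Within the type 17 program some members, Il17a and Il17f among them, rose, while others fell or did not pass the test. Il17a, the signature cytokine of these cells (NM_010552, chromosome 1, 20730905 to 20734496), rose 9.98-fold in mean TPM, from 60.8 ± 31.6 to 607 ± 150 (log2 fold change 3.38, SE 0.32, limma adjusted p = 0.000522). Il17f rose 2.51-fold, from 110 ± 32.7 to 277 ± 122 TPM (limma adjusted p = 0.0356). The epithelial barrier cytokine Il22 fell from 40.3 ± 18.4 to 15.4 ± 4.39 TPM (limma adjusted p = 0.0325), the chemokine receptor Ccr6 from 177 ± 59.1 to 42.9 ± 6.73 (limma adjusted p = 0.00177) and the epidermal growth factor family member Areg from 272 ± 84.2 to 123 ± 22.4 (limma adjusted p = 0.0163). The leukotriene B4 receptor Ltb4r1 (220 ± 30.8 to 479 ± 71.0 TPM), the transcription factor Batf (41.0 ± 2.997 to 77.5 ± 3.30 TPM) and Maf, a transcription factor of the lineage (174 ± 51.0 to 300 ± 28.8 TPM), rose. The interleukin-23 receptor Il23r was at 85.5 ± 30.4 TPM in control and 63.5 ± 22.8 in S. aureus libraries, the interleukin-1 receptor Il1r1 at 21.8 ± 7.41 and 19.3 ± 5.49, and the kinase Blk at 107 ± 27.4 and 72.2 ± 11.8, with limma adjusted p of 0.452, 0.764 and 0.150. Csf2 was at 98.8 ± 27.1 and 189 ± 65.1 TPM (limma adjusted p = 0.0761), and the proliferation marker Mki67 at 25.6 ± 6.18 and 36.2 ± 10.8 (0.300). Ifng, listed at 0.218 ± 0.377 and 0.907 ± 1.29 TPM, was below the filter and not tested.

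Of 27 measured type 17 genes, 6 were higher, 3 lower and 18 not past the threshold, and 6 and 5 when adjusted over the list alone; the list as a whole did not stand apart from other genes (camera adjusted p = 0.836). Its median (-0.13) and mean (-0.06) log2 fold change lay below 0 while camera placed it upward, relative to all genes. Without single libraries the call of Il17f was kept in 2 of 7 fits (limma adjusted p 0.0313 to 0.114), that of Il22 in 1 of 7 (0.0354 to 0.0829) and that of Maf in 2 of 7 (0.0368 to 0.0946). Il22 also lost its call with median-ratio scaling (limma adjusted p = 0.105), and Areg with a keratinocyte marker mean as a covariate (0.0538). The receptor complex genes Cd3e, Cd3g, Cd3d and Cd247, the 4 members measured of their list, gave 0 calls by limma (1 higher and 0 lower when adjusted over the list alone).

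**Figure D2:**
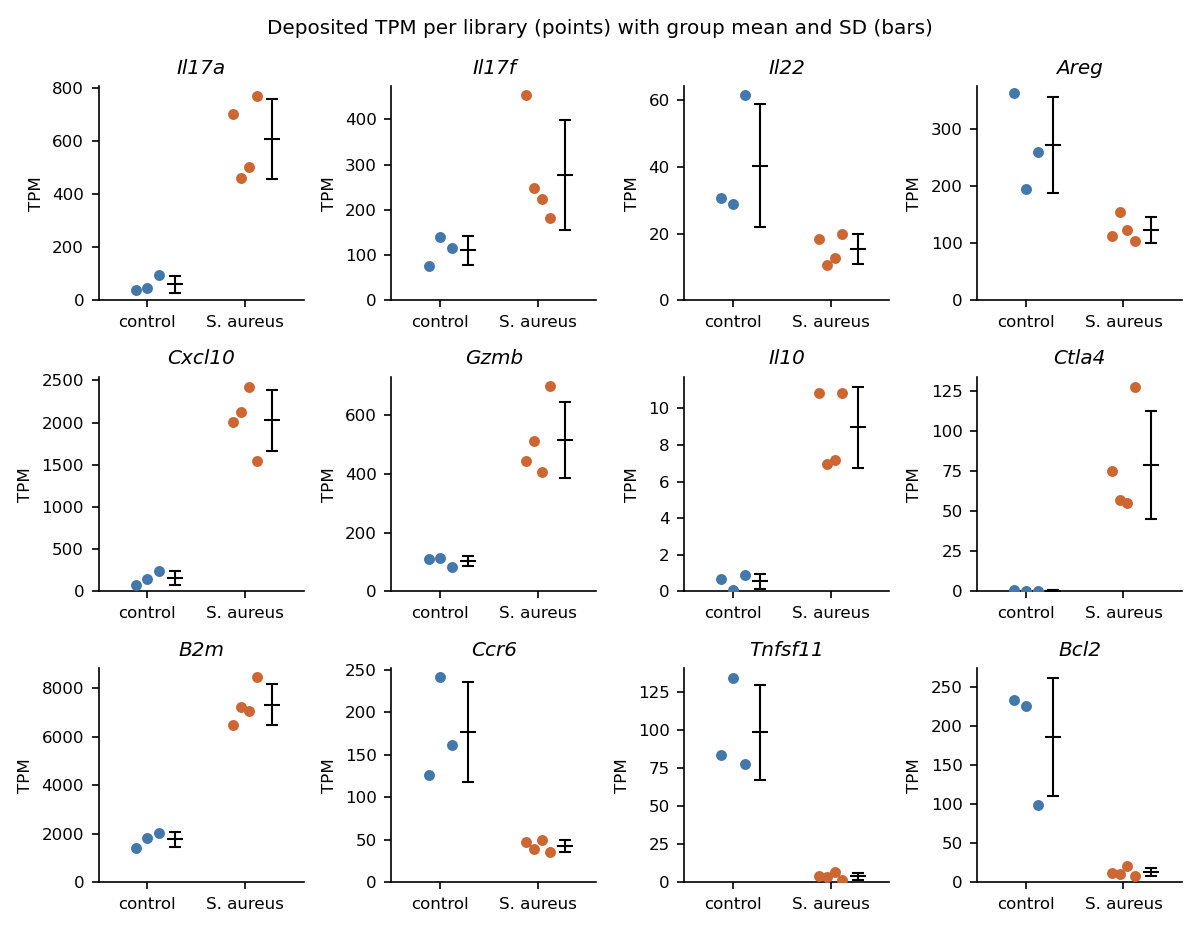
Deposited TPM (vertical axes, each from 0) of 12 genes in the 3 control and 4 S. aureus libraries, each point a library, with the group mean and SD as bars. Il17a lay at 607 ± 150 TPM in S. aureus against 60.8 ± 31.6 in control libraries, and Ccr6 at 42.9 ± 6.73 against 177 ± 59.1.

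Interferon-inducible genes had the largest median change of the 28 program lists. Of 35 measured members of the interferon response list, 24 were higher and 0 lower (27 and 0 when adjusted over the list alone), with a median log2 fold change of 2.03. The guanylate-binding protein gene Gbp2 rose 17.3-fold in mean TPM, from 4.02 ± 0.475 to 69.5 ± 6.11, and Igtp, an immunity-related GTPase, from 31.7 ± 2.60 to 305 ± 48.6, beside Iigp1 and Gbp3 above. Genes of antigen presentation on MHC class I rose with them: 14 of 18 were higher and 0 lower (16 and 0 when adjusted over the list alone). The light chain B2m rose 4.12-fold, from 1773 ± 311 to 7306 ± 838 TPM, and the immunoproteasome subunits Psmb9 (29.6 ± 5.42 to 162 ± 19.2), Psmb10 (170 ± 31.0 to 808 ± 114) and Psmb8 (548 ± 102 to 1531 ± 107) rose as well. Camera gave adjusted p = 7.08e-28 for the interferon list and 3.93e-16 for the MHC class I list; the adjusted p was 0.106 for each with an estimated correlation.

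The type 1 and cytotoxic list held 6 higher and 0 lower genes of 20 measured (7 and 1 when adjusted over the list alone). Gzmb, encoding granzyme B, rose 5.03-fold, from 102 ± 16.8 to 514 ± 130 TPM (limma adjusted p = 0.000427). The homeobox gene Hopx rose from 80.5 ± 42.1 to 235 ± 21.9 TPM, the type 1 lineage factor Tbx21 from 0.376 ± 0.232 to 6.88 ± 3.12 and the chemokine Ccl5 from 0.0240 ± 0.0416 to 4.01 ± 1.35. Control replicate 1 stood apart in this list, with a mean log2(TPM + 1) of 5.24 against 3.60 and 3.29 in control replicates 2 and 3 and 4.19 to 4.43 in the S. aureus libraries. The list was called (camera adjusted p = 0.0368), its adjusted p was 0.572 with an estimated correlation, and it kept its call in 4 of 7 fits without single libraries (0.000164 to 0.172), losing it without control replicate 2, control replicate 3 or S. aureus replicate 4. It was called in 11 of 23 other settings. Among the rest, it was not called by camera on ranks (adjusted p = 0.194), after quantile normalization (0.0977) or by fry (0.121).

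Among effector cytokines and chemokines, genes moved in both directions: 5 of 25 were higher and 9 lower (6 and 12 when adjusted over the list alone). The chemokine Cxcl10, which attracts Cxcr3-bearing cells, rose 12.9-fold, from 157 ± 81.7 to 2025 ± 366 TPM (log2 fold change 3.80, SE 0.34, limma adjusted p = 0.000369). Tnfsf14 (LIGHT) fell 6.27-fold, from 146 ± 28.5 to 23.2 ± 3.98 TPM, beside the fall of Tnfsf11. In the tissue repair list 1 of 19 genes was higher and 4 lower (2 and 6 when adjusted over the list alone): the regulatory cytokine Il10 rose from 0.553 ± 0.422 to 8.96 ± 2.20 TPM. By contrast Tnfaip8l2 (360 ± 62.4 to 165 ± 21.2), Lif (6.96 ± 1.76 to 1.23 ± 1.05) and Pdgfb (12.4 ± 3.09 to 4.26 ± 1.18) fell. In the type 2 list 1 of 5 was higher and 1 lower (1 and 2 when adjusted over the list alone): the TSLP receptor Crlf2 rose from 23.2 ± 6.48 to 42.0 ± 5.22 TPM, and the interleukin-4 receptor Il4ra fell from 43.9 ± 9.20 to 20.2 ± 2.22. These 3 lists did not stand apart by camera (adjusted p = 0.318, 0.402 and 0.590). Calls of single genes rested on few libraries for Crlf2, called in 2 of 7 fits without single libraries (limma adjusted p 0.0161 to 0.107), and ended for Lif without control replicate 1 or 2 and for Pdgfb without control replicate 2 (up to 0.0687 and 0.0702). Median-ratio scaling ended the call of Tnfaip8l2 (limma adjusted p = 0.0550) and the keratinocyte covariate that of Il4ra (0.0650). The effector list passed in 4 of 23 other settings, all downward: without S. aureus replicate 4 (camera adjusted p = 0.0478), also without control replicate 1 (0.0346), with a replicate block (0.0485) and by fry (0.0237). All of these but fry take S. aureus replicate 4 out of the group contrast, so they are not separate support.

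Some receptors of activation and restraint rose and others fell, while most did not pass the test. In this list 7 of 24 genes were higher, 4 lower and 13 not past the threshold (7 and 6 when adjusted over the list alone): Ctla4 rose as above, the costimulatory receptor Cd28 rose from 0.875 ± 0.303 to 7.64 ± 1.96 TPM and the transcriptional repressor Prdm1 (Blimp-1) from 2.82 ± 0.228 to 16.2 ± 4.47. The adhesion receptor Cd96 fell from 26.8 ± 10.9 to 5.49 ± 0.263. Of 16 tissue residency genes, 2 were higher and 5 lower (3 and 9 when adjusted over the list alone). The skin-homing receptor Ccr8 fell 5.08-fold, from 293 ± 94.1 to 57.7 ± 10.4 TPM, Bhlhe40 from 403 ± 114 to 196 ± 15.9 and the integrin Itgb7 from 477 ± 92.7 to 274 ± 11.2. Cd69, which holds cells in tissue, fell from 712 ± 82.2 to 464 ± 52.2 TPM (limma adjusted p = 0.0232). Of 18 egress and circulation genes, 1 was higher and 3 lower (1 and 6 when adjusted over the list alone): the egress receptor S1pr1 fell from 115 ± 33.6 to 50.6 ± 14.0 TPM, the T cell factor Tcf7 from 36.5 ± 8.19 to 8.53 ± 2.10 and Klf3 from 10.8 ± 4.39 to 2.29 ± 0.867, while S1pr4 rose from 27.2 ± 3.77 to 61.7 ± 10.9. Of 28 chemokine receptor and adhesion genes, 5 were higher and 5 lower (6 and 12 when adjusted over the list alone). The prostaglandin D2 receptor Ptgdr2 fell from 46.0 ± 4.60 to 17.3 ± 2.80 TPM. Of 29 T cell receptor signalling genes, 1 was higher and 2 lower (the same numbers when adjusted over the list alone): Cd28 rose, and the adaptors Sla (57.9 ± 13.5 to 28.7 ± 6.99 TPM) and Lcp2 (89.7 ± 16.1 to 45.6 ± 11.2) fell. Camera did not separate these 5 lists from other genes (adjusted p = 0.163, 0.0840, 0.198, 0.550 and 0.324), although the residency list passed without control replicate 2 (0.0477), with quantile normalization (0.0234) and with array weights (0.0298). Without single libraries Cd69 was called in 2 of 7 fits (limma adjusted p 0.0127 to 0.0872), S1pr1 in 3 (0.0188 to 0.103), Sla in 4 (0.0295 to 0.104), Lcp2 in 3 (0.0232 to 0.108) and Itgb7 in 6, ending without control replicate 2 (0.0593). Median-ratio scaling ended the call of Cd69 (limma adjusted p = 0.236), and the keratinocyte covariate those of Bhlhe40 (0.0579) and Klf3 (0.0607).

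Genes of the respiratory chain that passed the test over all genes rose by modest amounts, with 1 exception, while most did not pass it. Of 70 measured oxidative phosphorylation genes, 28 were higher and 1 lower (38 and 1 when adjusted over the list alone), with a median log2 fold change of 0.49. The complex I subunits Ndufa1 (303 ± 33.5 to 700 ± 99.8 TPM), Ndufb7 (194 ± 28.8 to 341 ± 22.98) and Ndufs6 (51.5 ± 4.85 to 93.5 ± 8.04) and the complex III subunit Uqcr10 (259 ± 33.6 to 585 ± 111) rose. Ribosomal protein genes, listed in advance as a sign of RNA quality, rose alongside: 33 of 76 were higher and 0 lower (39 and 0 when adjusted over the list alone), with a median of 0.53, and every S. aureus library (7.60 to 7.71 mean log2(TPM + 1)) lay above every control library (7.07 to 7.21). Camera gave adjusted p = 1.47e-14 for oxidative phosphorylation (0.386 with an estimated correlation) and 9.60e-17 for ribosomal proteins (adjusted p = 0.0914 with an estimated correlation). Glycolysis genes moved both ways, 2 of 23 higher and 1 lower (3 and 2 when adjusted over the list alone; camera adjusted p = 0.264; median 0.12, mean -0.03): Tpi1 rose from 424 ± 63.7 to 898 ± 332 TPM and Pgam1 from 27.4 ± 1.49 to 41.6 ± 3.35. Hexokinase 2 (Hk2) fell from 20.2 ± 4.33 to 7.79 ± 2.15. Of 23 hypoxia genes, 3 were higher and 1 lower (3 and 3 when adjusted over the list alone; camera adjusted p = 0.142): Hif1a rose from 25.3 ± 6.78 to 66.7 ± 6.81 TPM, Ankrd37 from 18.1 ± 6.76 to 71.3 ± 29.9 and Bnip3 from 7.92 ± 1.55 to 17.1 ± 5.13, and Bhlhe40 fell. Without single libraries Tpi1 was called in 3 of 7 fits (limma adjusted p 0.0174 to 0.122), Pgam1 in 1 (0.0382), Bnip3 in 2 (0.0424 to 0.124) and Hk2 in 5, ending without control replicate 1 or 2 (up to 0.0743).

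Genes of lipid synthesis and uptake that passed the test over all genes fell, while most did not pass it. In the cholesterol and fatty acid synthesis list 0 of 31 genes were higher and 13 lower by limma (0 and 23 when adjusted over the list alone), with a median log2 fold change of -0.97. The stearoyl-CoA desaturase Scd1 fell 9.17-fold, from 121 ± 79.0 to 13.2 ± 6.56 TPM, Elovl5 from 63.8 ± 7.19 to 24.2 ± 3.92, the farnesyl diphosphate synthase Fdps from 58.9 ± 11.4 to 26.8 ± 2.33 and the sterol sensor Insig1 from 16.7 ± 4.36 to 4.74 ± 1.53. In the lipid uptake and oxidation list 0 of 29 were higher and 7 lower by limma (1 and 10 when adjusted over the list alone); the fatty acid transporter Slc27a4 fell from 31.8 ± 14.8 to 5.88 ± 0.914 TPM, Plin3 from 118 ± 11.1 to 67.5 ± 2.79 and the acyl-CoA dehydrogenase Acadvl from 161 ± 9.22 to 87.7 ± 12.6. Camera adjusted p was 5.65e-09 and 0.00316, and with an estimated correlation the adjusted p was 0.311 and 0.534. Control replicates 1 and 2, in which keratinocyte transcripts were high, had synthesis list means of 4.12 and 4.27 log2(TPM + 1); control replicate 3, in which they were low, had 3.69, above the S. aureus range of 2.89 to 3.14. Median-ratio scaling ended the calls of Plin3 and Acadvl (limma adjusted p = 0.0723 and 0.0920), and the keratinocyte covariate that of Insig1 (0.0518). Scd1 was called in 19 of 20 other settings, and stood at 103, 208 and 53.2 TPM in control replicates 1, 2 and 3.

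Among genes induced by acute stimulation and stress, nearly all that passed the test also fell, while many did not pass it. The labels do not say how the groups were handled, so a difference in handling cannot be excluded for these genes. Of 33 immediate early genes, 1 was higher and 16 lower (2 and 22 when adjusted over the list alone). The AP-1 components Fos (585 ± 299 to 117 ± 36.0 TPM) and Fosb (76.4 ± 12.6 to 11.9 ± 4.76), the stress factor Atf3 (108 ± 20.4 to 26.6 ± 3.96) and the heat shock gene Hspa1a (431 ± 10.7 to 215 ± 43.9), whose reads its copy Hspa1b can share, fell. In the unfolded protein response list 0 of 26 were higher and 6 lower by limma (0 and 9 when adjusted over the list alone): the chaperone Hspa5 (BiP) fell from 2744 ± 478 to 1043 ± 324 TPM, Ppp1r15a from 531 ± 66.6 to 163 ± 13.9, Herpud1 from 310 ± 35.7 to 145 ± 14.9 and Pdia6 from 90.9 ± 11.9 to 50.7 ± 5.27. In the mTOR, Myc and ribosome biogenesis list 0 of 34 were higher and 10 lower by limma (0 and 11 when adjusted over the list alone): Myc fell from 45.4 ± 11.1 to 13.9 ± 4.90 TPM, Mycn from 7.81 ± 1.92 to 0.756 ± 0.788, the amino acid transporter chain Slc3a2 from 518 ± 9.09 to 190 ± 41.8 and the polyamine enzyme Odc1 from 2146 ± 461 to 968 ± 77.8. In the glucocorticoid and TGF-β response list 0 of 19 were higher and 3 lower by limma (0 and 3 when adjusted over the list alone): Tsc22d3 (GILZ) fell from 567 ± 66.5 to 216 ± 78.9 TPM, Dusp1 from 2110 ± 162 to 1096 ± 291 and Klf9 from 6.39 ± 1.41 to 1.44 ± 0.315. Camera adjusted p for these 4 lists was 4.49e-08, 0.000216, 0.00128 and 0.00316, and with an estimated correlation the adjusted p was 0.386, 0.311, 0.534 and 0.577. Among the controls these lists were lowest in control replicate 3, where keratinocyte transcripts were low: 7.41, 5.87, 4.63 and 4.25 mean log2(TPM + 1), against 7.84 and 7.89, 6.01 and 6.24, 4.84 and 5.04, and 4.84 and 4.84 in control replicates 1 and 2. The highest S. aureus values were 7.003, 5.64, 4.43 and 4.23, so for the glucocorticoid and TGF-β list control replicate 3 lay next to them. Receptors for neural and stress signals moved individually: of 11 measured, 0 were higher and 4 lower by limma (1 and 4 when adjusted over the list alone; camera adjusted p = 0.264), with the calcitonin gene-related peptide co-receptor Ramp1 down from 87.7 ± 26.9 to 43.4 ± 6.56 TPM, beside Adrb1 and Ramp3. Without single libraries Dusp1 lost its call without control replicate 1 or 2 (limma adjusted p up to 0.0926), Tsc22d3 and Pdia6 without control replicate 2 (0.0580 and 0.0550), and Ramp1 was called in 3 of 7 fits (0.0146 to 0.0927). Median-ratio scaling ended the call of Hspa1a (limma adjusted p = 0.0722) and the keratinocyte covariate that of Myc (0.0579), and fry did not call the glucocorticoid and TGF-β list (adjusted p = 0.121).

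Genes of cell survival and inflammatory signalling moved in both directions. In the apoptosis and survival list 1 of 23 genes was higher and 5 lower (2 and 5 when adjusted over the list alone): the caspase Casp1 rose 15.6-fold, from 2.57 ± 1.82 to 40.1 ± 7.64 TPM, while the cyclin-dependent kinase inhibitor Cdkn1a (p21) fell 4.56-fold, from 857 ± 8.69 to 188 ± 15.3 (limma adjusted p = 1.99e-05), Mcl1 from 409 ± 61.0 to 235 ± 11.9, and Bcl2 as above. The list's median was 0.28 and its mean -0.11, and it did not stand apart (camera adjusted p = 0.924). Of 28 genes of signalling by IL-1, IL-23, IL-7 and IL-18, 1 was higher and 6 lower (2 and 8 when adjusted over the list alone; camera adjusted p = 0.284): the decoy receptor Il1r2 rose from 1.06 ± 0.754 to 10.7 ± 4.15 TPM, and Nfkbiz (383 ± 97.49 to 145 ± 35.6) and Myd88 (122 ± 14.1 to 77.5 ± 2.10) fell. Of 28 NF-κB targets, 3 were higher and 5 lower (5 and 8 when adjusted over the list alone; camera adjusted p = 0.318): Irf1 rose from 84.9 ± 4.31 to 361 ± 95.6 TPM and Bcl2a1a, one of several near-identical copies, from 129 ± 27.1 to 370 ± 78.7, while Nfkbid (1167 ± 206 to 322 ± 85.2) and Nfkbie (348 ± 49.1 to 156 ± 30.5) fell. In the autophagy and lysosome list 1 of 27 was higher and 7 lower (2 and 12 when adjusted over the list alone): Gabarap rose from 473 ± 23.3 to 722 ± 74.9 TPM, and the lysosomal enzymes Ctsd (293 ± 18.3 to 162 ± 21.4), Gla (48.5 ± 32.8 to 12.1 ± 0.364) and Hexa (7.99 ± 0.316 to 3.60 ± 0.9996) fell. This list was called (camera adjusted p = 0.0295, and 0.534 with an estimated correlation). It lost its call without control replicate 3 or S. aureus replicate 1 (up to 0.0588) and with median-ratio scaling (0.0879). The call also ended with limma voom (camera adjusted p = 0.0761) and with the keratinocyte covariate (0.0715). Without single libraries Myd88 was called in 4 of 7 fits (limma adjusted p 0.0205 to 0.0686), Hexa in 2 (0.0388 to 0.102) and Gabarap in 6, ending without control replicate 2 (0.0599). Median-ratio scaling ended the call of Ctsd (limma adjusted p = 0.0758), and the keratinocyte covariate those of Gla (0.0867) and Mcl1 (0.0503).

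Few single cell cycle genes changed. Of 43 G2/M genes, 1 was higher and 0 lower by limma (1 and 0 when adjusted over the list alone): the cyclin Ccnb1 rose from 6.77 ± 2.70 to 19.96 ± 4.86 TPM. The list was called upward (camera adjusted p = 0.00923; adjusted p = 0.572 with an estimated correlation) at a median log2 fold change of 0.15, but not without control replicate 1 (0.145) or by fry (0.194). Of 37 S phase genes, 1 was higher and 0 lower by limma (0 and 0 when adjusted over the list alone; camera adjusted p = 0.163): the licensing inhibitor Gmnn rose from 19.0 ± 4.58 to 43.8 ± 14.5 TPM, called in 3 of 7 fits without single libraries (limma adjusted p 0.0335 to 0.106). The S phase list passed without S. aureus replicate 2 (camera adjusted p = 0.0467), and leaving out control replicate 1 and S. aureus replicate 4 together ended the call of Ccnb1 (limma adjusted p = 0.0593).

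**Figure D3:**
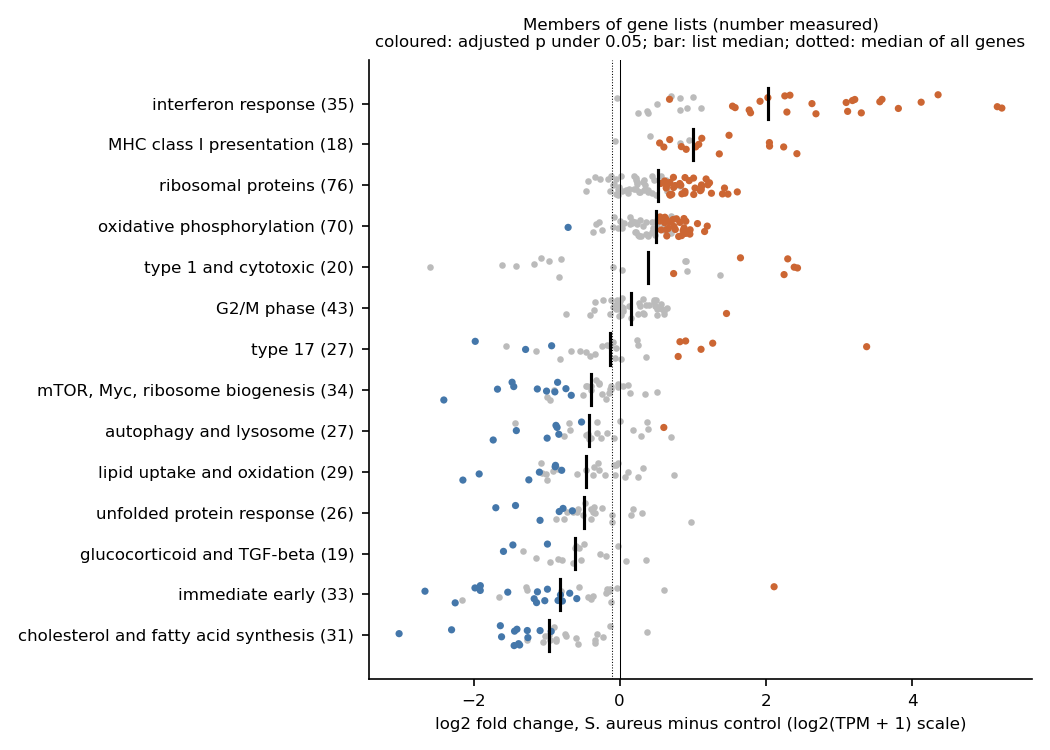
Log2 fold change (S. aureus minus control, on the log2(TPM + 1) scale, horizontal axis) of every measured member of 14 gene lists, coloured where limma called the gene, with a bar at each list's median and a dotted line at the median of all genes (-0.11). List medians ran from -0.97 for cholesterol and fatty acid synthesis to 2.03 for the interferon response.

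Transcripts of other skin cells were present in all libraries and differed between them. Keratinocyte markers were high in control replicates 1 and 2 (mean log2(TPM + 1) of 4.91 and 5.34 over 16 genes), while control replicate 3 (3.15) lay within the S. aureus range (2.95 to 4.28). Krt14, a keratin of basal keratinocytes, was at 230 and 203 TPM in control replicates 1 and 2, 19.6 in control replicate 3 and 19.7 to 55.5 in the S. aureus libraries (limma adjusted p = 0.218), and Sfn fell from 336 ± 72.8 to 204 ± 21.7 TPM (limma adjusted p = 0.0347, called in 1 of 7 fits without single libraries, 0.0114 to 0.130). The keratinocyte list had 0 higher and 4 lower genes by limma (0 and 5 when adjusted over the list alone). Its camera adjusted p was 0.0484, and 0.879 with an estimated correlation, and its exact permutation p was 0.229. Without single libraries the list was called in 2 of 7 fits (camera adjusted p 8.27e-05 to 0.141), and fry did not call it (adjusted p = 0.497). Fibroblast markers followed the same libraries (4.42 and 4.10 in control replicates 1 and 2, 1.86 in control replicate 3, 2.59 to 4.03 in S. aureus), with Thy1 at 484 ± 133 and 383 ± 77.2 TPM, which T cells also express, and Dcn at 19.8 ± 15.4 and 11.8 ± 11.7. Control replicate 1 alone held high levels of transcripts shared by dendritic epidermal T cells and natural killer cells: Nkg7 was at 6015 TPM there and 264 and 263 in the other 2 controls, Cd7 at 2215 against 101 and 105, Fcer1g at 482 against 8.95 and 8.67, and Prf1 at 139 against 4.02 and 0.508. The epidermal T cell list, which holds Cd7 but not Nkg7, had a mean of 6.75 in control replicate 1 and 4.41 to 5.09 elsewhere.

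Among the remaining lists for other cell types, S100a8 and S100a9 made up 2 of the 3 measured neutrophil genes, and the third, Il1b, was not called. Cd79b, a B cell receptor chain, rose from 19.1 ± 1.66 to 83.0 ± 4.74 TPM (limma adjusted p = 0.000102), with the plasma cell marker Sdc1 at 29.8 ± 12.6 and 18.4 ± 3.58. In the list for natural killer cells and group 1 innate lymphoid cells, Irf8 rose from 8.71 ± 2.54 to 37.8 ± 14.97 TPM, and its members Tbx21 and Cma1 stand in other lists too. This list had only 5 measured genes, of which 2, Irf8 and Tbx21, were called higher. Its member Prf1 had a log2 fold change of -1.18 (limma adjusted p = 0.606). In the group 2 innate lymphoid list the neuropeptide gene Calca fell 3.05-fold, from 109 ± 20.6 to 35.9 ± 5.90 TPM (limma adjusted p = 0.00216), beside Areg. Xcr1, a dendritic cell chemokine receptor, rose from 28.3 ± 5.45 to 56.1 ± 10.2 TPM and Cst3 was at 443 ± 31.3 and 601 ± 90.6. The endothelial adhesion molecule Pecam1 rose from 1.92 ± 0.835 to 7.41 ± 2.81 with Egfl7 at 5.67 ± 1.59 and 4.74 ± 0.459. The myelin gene Mbp fell from 15.5 ± 4.32 to 5.89 ± 1.59 with Pmel at 1.16 ± 1.29 and 1.63 ± 0.439. Apoe was at 441 ± 255 and 176 ± 85.9 TPM. The mast cell proteases Mcpt4 and Cma1 were at 13.6 ± 23.6 and 11.2 ± 8.15 and at 8.19 ± 13.8 and 13.4 ± 8.30. The near-identical haemoglobin genes Hba-a1 and Hba-a2 were at 308 ± 281 and 261 ± 221 and at 306 ± 280 and 260 ± 220. By the exact permutation test over 16 lists, those for neutrophils, B and plasma cells, αβ T cells, group 2 innate lymphoid cells, natural killer cells and ribosomal proteins each reached the smallest possible p, 0.0286 (adjusted p = 0.0762). The list mean was lower in S. aureus libraries for group 2 innate lymphoid cells (-0.55) and higher for the other 5. In the αβ T cell list the rise of the mean (0.40 over 6 genes) came from Ctla4 (log2 fold change 5.93), since the median was -0.42, Tcf7 and Cd40lg were lower, and camera placed the list downward (adjusted p = 0.954). The epidermal T cell list had a median of -0.82 and a mean of -0.44 while camera placed it upward (adjusted p = 0.975). The lists for fibroblasts (p = 0.629), endothelium (0.800), macrophages (0.257), dendritic cells (0.514), mast cells (0.400), epidermal T cells (0.800), melanocytes and Schwann cells (0.771), erythrocytes and platelets (0.657) and nuclear non-coding RNA (0.0857) had larger exact permutation p. Calls of single genes here ended without control replicate 2 for Irf8 and Mbp (limma adjusted p = 0.0644 and 0.0873) and without S. aureus replicate 1 for Mbp (0.0522). Without single libraries Xcr1 was called in 3 of 7 fits (0.0117 to 0.0630) and Pecam1 in 2 (0.00738 to 0.0960).

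**Figure D4:**
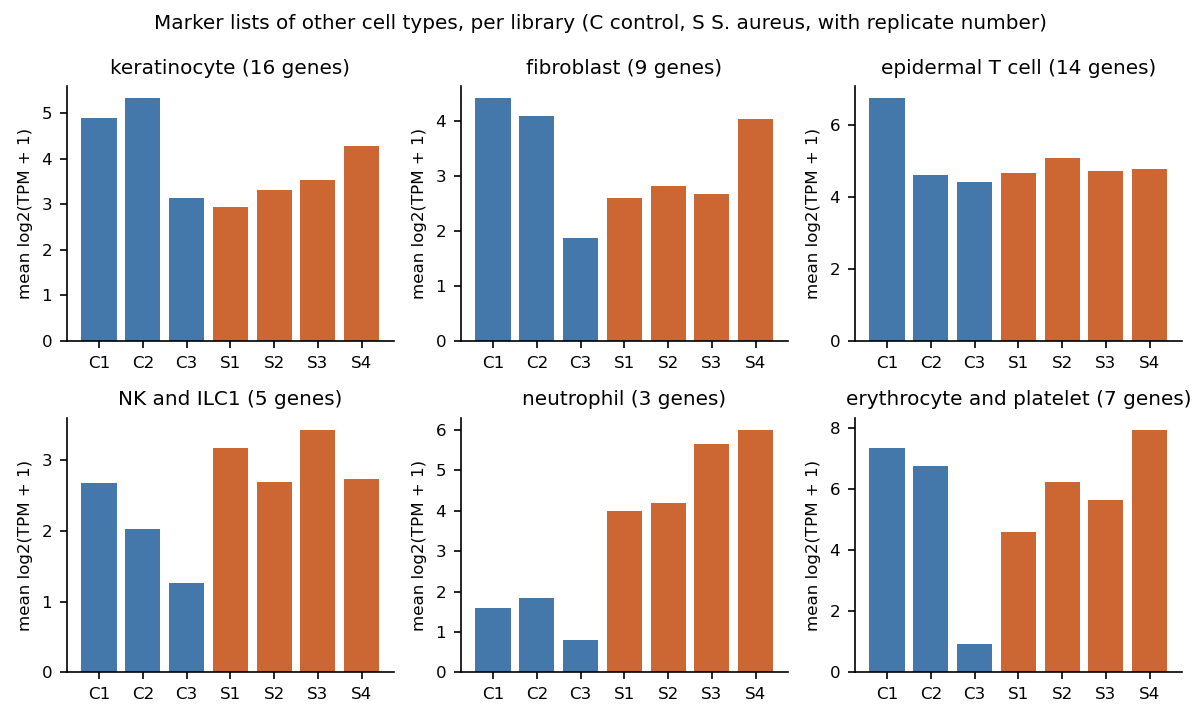
Mean log2(TPM + 1) (vertical axes, each from 0) of 6 marker lists for other cell types in each library, control replicates 1 to 3 and S. aureus replicates 1 to 4. Keratinocyte markers stood at 4.91 and 5.34 in control replicates 1 and 2 against 3.15 in control replicate 3, and epidermal T cell markers at 6.75 in control replicate 1.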

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

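The tests of neutrophil and keratinocyte RNA for S100a8 and S100a9, on each scale, the measurement of control replicate 3 on left-out libraries and the fits with a keratinocyte covariate were chosen only after the results were seen.

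Across 35 splits of the 7 libraries into 3 and 4, only 1, the real one, gave as many called genes: 1416, against at most 4 in any other split. This is the strongest result that 35 splits can give, an exact permutation p of 0.0286. It argues against chance division of the libraries without excluding it. Every other split mixes the 2 groups, which raises its spread, so the gap from 4 to 1416 does not measure strength. The genes lower in the S. aureus libraries could in part reflect keratinocyte RNA, which was high in control replicates 1 and 2. Without control replicate 3, 919 genes were called lower; in control replicate 3, low in keratinocyte transcripts, they lay a median of 0.76 log2 above the S. aureus mean, a value that decides nothing, since the genes were chosen for low values in the same S. aureus libraries. Next, 919 genes were chosen on 1 of control replicates 1 and 2 and 2 S. aureus libraries, and measured on the others. Over 12 choices control replicate 3 lay a median of 0.47 to 0.76 log2 above the left-out S. aureus libraries (all tested genes: -0.17 to 0.03). The left-out control lay 0.91 to 1.18 above them (all tested genes: 0.03 to 0.34). The share of 51.1% to 67.2% rests on a single library. It was formed without taking off the values of all tested genes, which were higher for the left-out control. With the keratinocyte marker mean as a covariate, 263 genes were called lower and 318 higher, of which 257 and 297 were among those called without it. How much of the lower set keratinocyte RNA accounts for cannot be told apart from the association itself with 3 controls, and a biological response to S. aureus stays open.

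S100a8 and S100a9 are abundant in neutrophils and in stimulated keratinocytes. Against neutrophil RNA, 8 granulocyte transcripts (Retnlg, Csf3r, Cxcr2, Ly6g, Mmp8, Camp, Ngp and Ltf) summed to 0.530 TPM in the S. aureus libraries, 0.265% of the 199.8 TPM of S100a8 and S100a9. Because that TPM is scaled by genomic span, the share was recomputed. It was 0.318% on exonic length, under the 1% set as the bound. In read units without any scaling by length it was 1.38% (111 against 8018), above that bound. The scales thus disagree, and a contribution of neutrophils of unknown size stays possible. Against a larger amount of keratinocyte RNA, the 16 measured keratinocyte markers had a median log2 fold change of -0.91 (SD 0.95), the highest of them 1.29. A smaller amount of RNA from keratinocytes with a changed content remains possible and was not tested. The epidermal genes Sprr2d, listed at 0 TPM in the 3 controls and at 1.08 to 34.1 in the S. aureus libraries, and Sprr2e (0.727 against 10.3 TPM, limma adjusted p = 0.0350) were higher too. Across S. aureus replicates 1 to 4 the keratinocyte list means were 2.95, 3.32, 3.53 and 4.28 log2(TPM + 1). S100a8 was at 37.5, 87.1, 297 and 206 TPM in these libraries, lower in replicates 1 and 2 than in replicates 3 and 4. Control replicates 1 and 2 had higher list means, 4.91 and 5.34, with S100a8 at 0 and 2.54 TPM. Expression by the sorted T cells themselves stays open as a biological explanation.

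Ribosomal protein and oxidative phosphorylation genes are short and highly expressed, so a bias by transcript length, GC content or level may have raised both. The median log2 fold change of the 76 ribosomal protein genes, 0.53, lay above 99.96% of 10000 random lists matched gene by gene on exonic length, GC content and mean level, whose central 95% ended at 0.42; that of the 70 oxidative phosphorylation genes, 0.49, lay above 99.8%, with the same upper end of 0.42. The matched lists themselves had medians of 0.28 and 0.28, so part of each rise was shared by genes alike in these properties. The random lists were drawn gene by gene, so their spread leaves out any tendency of the listed genes to move together. With an estimated correlation, camera adjusted p was 0.0914 for ribosomal proteins and 0.386 for oxidative phosphorylation. The bias was therefore argued against only weakly, and only as the whole origin. A difference in handling or library preparation between the groups was not given in the labels and cannot be excluded, and a change in the cells stays a hypothesis.

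In 190 groups of values over the 4 S. aureus libraries, 23 had 1 library far from the other 3, where chance gives about 5% of groups; the gap is given as a share of the whole range for 22 of them. S. aureus replicate 4 was the library apart in TPM of AW112010 (0.866, highest), Adrb1 (0.831, lowest), Blk (0.926, lowest), Irf1 (0.844, lowest), Psmb9 (0.897, highest), Ndufa1 (0.853, highest), Uqcr10 (0.842, highest), Ankrd37 (0.936, highest), Hspa5 (0.974, highest), Slc3a2 (0.858, lowest) and Dcn (0.950, highest). It was also apart in the list means of signalling by IL-1, IL-23, IL-7 and IL-18 (0.835, lowest), immediate early genes (0.874, lowest), T cell receptor signalling (0.865, lowest), oxidative phosphorylation (0.917, highest), the glucocorticoid and TGF-β response (0.914, lowest), apoptosis and survival (0.830, lowest) and fibroblast markers (0.851, highest), and in the number of genes at 1 TPM or more (0.963, lowest, at 10207). S. aureus replicate 1 was apart in Ms4a4b (0.845, lowest), and S. aureus replicate 2 in Crlf2 (0.948, highest) and in the glycolysis list (0.867, highest). Without S. aureus replicate 4, 861 genes were called higher and 742 lower.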

How the results depend on the processing

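The fits with limma voom, with the keratinocyte covariate and without control replicate 1 and S. aureus replicate 4 together were chosen after the data were seen. Under each of the 20 other gene settings, every one of the 1416 called genes that was tested kept its direction, and 0 were called the opposite way by limma. This was largely fixed in advance and says little about stability. For 1412 of these genes the groups did not overlap, so leaving out libraries could not turn their direction. Changing the filter, the intensity trend or the robust variance model leaves the fold change itself as it was. Of the 119 named genes called, 76 were called in each other setting that tested them and 91 in each of the 7 fits without 1 library. Without single libraries the number of genes higher ran from 360 (without control replicate 2) to 861 (without S. aureus replicate 4) and the number lower from 328 (without control replicate 2) to 919 (without control replicate 3); the other values were 423 and 442 without control replicate 1, 430 and 508, 429 and 484, and 394 and 435 without S. aureus replicates 1, 2 and 3. Fewer libraries lower the power of each such fit. With the keratinocyte covariate 318 were higher and 263 lower, and the cause was not tested. Voom on recovered units gave 647 and 733, and leaving out control replicate 1 and S. aureus replicate 4 together gave 713 and 571. Of 28 program lists, 5 were called higher and 7 lower; with an estimated correlation 0 were called higher and 0 lower, 4 lists had an unadjusted p under 0.05, and fry called 3 higher and 7 lower.

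The replicate numbers did not pair the libraries: same-numbered libraries had correlations of deviations of -0.050, -0.012 and 0.008. With the number as a replicate block 489 genes were higher and 439 lower. Replicate number 4 occurs only among the S. aureus libraries, so the block fits that library by itself and takes it out of the group contrast. The block put Il1r1 at 0.0556 log2, the same value as without S. aureus replicate 4. It turned the direction of the epidermal T cell list (camera adjusted p = 0.823), as leaving out S. aureus replicate 4 did (0.915). These shifts are therefore no effect of pairing alone.

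Results that changed direction were not called in either direction, with 1 exception, fibroblast markers under the keratinocyte covariate (adjusted p = 0.0278); the cause was not tested. Without single libraries Il1r1 ran from -0.30 to 0.0834, and it was 0.0047 with array weights. Dcn ran from -1.54 to 0.0787 and was 0.98 with the covariate. Without control replicate 1 and S. aureus replicate 4, Fcer1g was 0.13 and Prf1 0.61, and Prf1 was 0.0861 with the covariate. Without single libraries Fcer1g ran from -2.64 to 0.185, Cd7 from -2.14 to 0.0802, Prf1 from -2.56 to 0.714, Hba-a1 from -1.15 to 2.94 and Hba-a2 from -1.15 to 2.93. For lists, adjusted p where the direction turned were, for type 17, 0.742 with quantile normalization, 0.343 without the 2 libraries, 0.821 by ranks and 0.992 by fry; for apoptosis and survival, 0.467 at a mean of 5 TPM, 0.819 with the covariate, 0.806 without the 2 libraries and 0.251 by fry; for epidermal T cell markers, 0.999 at pseudocount 5, 0.811 with median-ratio scaling, 0.680 with quantile normalization, 0.812 with array weights and 0.658 by ranks; and for αβ T cell markers, 0.520 by fry. Without single libraries the adjusted p ran from 0.393 to 0.839 for type 17, 0.778 to 0.981 for apoptosis and survival, 0.0463 to 0.921 for fibroblast markers, 0.0842 to 0.981 for epidermal T cell markers, 0.817 to 0.981 for αβ T cell markers and 0.0807 to 0.82915 for erythrocyte and platelet markers.

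Lists not called otherwise passed in some settings. Hypoxia passed without a filter (adjusted p = 0.0420), at a mean of 5 TPM (0.0396) and with the keratinocyte covariate (0.0371), and neural and stress receptors at a mean of 5 TPM (0.0309). Group 2 innate lymphoid markers passed at a mean of 5 TPM (0.0288) and by fry (0.0084). Natural killer markers, a list of 5 measured genes, passed at pseudocount 0.1 (0.0429), without control replicate 1 (0.0368), also without S. aureus replicate 4 (0.0483), with the covariate (0.0278) and by fry (0.0290). With the covariate dendritic (0.0037), mast cell (0.0103) and erythrocyte markers (4.02e-08) passed, and mast cell markers also without control replicate 2 (0.00128). The cause was not tested.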

Other observations

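The test of the interferon lists and the scan of gene families were chosen only after the data were seen.

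Immunity-associated GTPases of the Gimap family, which act in lymphocyte survival, rose as a group: all 7 measured members were higher, with a median log2 fold change of 2.25. Gimap4 rose from 4.25 to 67.0 TPM and Gimap1 from 24.0 to 112 TPM. Of 9 guanylate-binding protein genes, 8 were higher and 0 lower by limma (median 3.10). Of 64 histone genes, 21 were higher and 0 lower by limma (median 1.33), many of them near-identical copies that can share reads. Hist1h1b rose from 19.5 to 101 TPM. The S phase list did not stand apart (camera adjusted p = 0.163), while the G2/M list was called upward (0.00923). Mki67 was not called (limma adjusted p = 0.300). Whether the histone rise reflects the cells or the preparation of polyadenylated RNA was not tested. Among families that fell, 5 of 7 genes of TNF superfamily ligands were lower, with Tnfsf9 (4-1BB ligand) down from 1006 to 228 TPM and Tnfsf8 from 24.7 to 4.35, as were 5 of 10 genes of the 70 kDa heat shock family and 6 of 11 Krüppel-like factors. Over 258 families of at least 6 genes, camera adjusted p was 1.21e-09 for Gimap, 4.19e-12 for guanylate-binding proteins, 1.31e-13 for histones, 0.000572 for TNF ligands, 0.000907 for heat shock and 0.000609 for Krüppel-like genes; with an estimated correlation the adjusted p was 0.255, 0.539, 0.638, 0.539, 0.351 and 0.994.

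A hypothesis from the interferon-inducible genes is that the response may be weighted toward interferon-γ rather than type 1 interferons. Of 22 measured genes weighted to interferon-γ (of 23 listed), 20 were higher and 0 lower by limma, with a median log2 fold change of 3.17; of 9 measured genes weighted to type 1 interferons, 3 were higher (median 1.01). The difference between the 2 list means rose by 1.48 log2 from control to S. aureus libraries, at the smallest p the exact permutation test can give (0.0286). The test does not settle the question: only 9 of 21 type 1 genes passed the filter, low genes have compressed fold changes on this scale, and the lists were written after genes such as Iigp1 and Gbp3 had been seen to rise. Irf7 was at 57.4 and 69.6 TPM and Isg15 at 63.6 and 104 TPM, neither called by limma (adjusted p = 0.409 and 0.230), whereas Irgm1 went from 39.8 to 362 TPM. Other members went against the weighting. The 3 called type 1 genes were Ifit1, from 1.34 to 38.3 TPM (log2 fold change 4.13, against 3.19 for Irgm1), Ifit3 (2.29) and Mx1 (1.58). Of the genes weighted to interferon-γ, Socs1 (-0.36) and Gbp8 (0.46) were not called.

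Some of the most abundant transcripts differed as well. The ferritin heavy chain Fth1 was at 24767 to 30465 TPM in control and 8398 to 10790 in S. aureus libraries. The ribosomal RNA precursor Rn45s, which polyadenylated selection leaves only in part, was at 6010 to 7253 TPM in control and 12087 to 14378 in S. aureus libraries. Tmsb4x reached 53094 TPM in S. aureus replicate 4 and 25704 to 27672 in the other 3 S. aureus libraries, against 17891 to 23847 in control libraries. For Actb the groups overlapped, at 16945 to 33576 TPM in control and 13754 to 26124 in S. aureus libraries.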
